A study of Mus musculus with 8 samples.

How the data were processed

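Ovarian cortex of mice at postnatal day 8 was used, and 4 input and 4 DCP1A RIP libraries were analysed. Per the labels' protocols, RNA bound to DCP1A was recovered with a Magna RIP kit, and libraries of total RNA were prepared with the SMARTer Stranded Total RNA-Seq Kit in its Pico input Mammalian version. Reads were placed on mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation and whether counting used strand are not given in the sources used here, so overlapping and antisense genes cannot be told apart. The deposited table by the authors held estimated counts (expected counts) of 23107 genes for 8 libraries, with at most 1.85% of a library's values not whole at a tolerance of 1e-09. These were rounded to whole numbers before testing. The design had been written for whole counts, and the same test was kept for the estimated counts. No further normalization of the deposited values was visible, since totals differed between libraries.

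Libraries held 13098153 to 25757618 counts, and between 14193 and 16834 genes had counts. The common biological coefficient of variation was 0.559, and the median standard error of a log2 fold change was 0.396, or 0.302 for genes above the median expression. Libraries correlated with a median r of 0.833 among inputs and 0.909 among RIP libraries, and 0.868 between the groups, over log2 CPM of tested genes. Values after ± are SDs or SEs over libraries. The floors of 3 counts cover counting error only. Whether molecular identifiers were used is not given, so amplified reads may not be independent molecules.

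Gene symbols of the table were matched to the RefSeq gene table of assembly GRCm38.p6, the patch release of mm10, which gave 20546 matches by symbol and 2260 by synonym and left 301 unmatched. Coordinates, biotypes and spans were taken from that table and are 1-based. Without a genome sequence, transcript length, 3' UTR length and GC content were not computed, and the annotated gene span was used in their place.

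RIP was compared with input in R 4.3.3. edgeR 4.0.16 was used with TMM factors, filterByExpr at its defaults (minimum count 10, minimum total 15), a robust quasi-likelihood fit and Benjamini-Hochberg adjustment with a threshold of 0.05, which left 14667 genes. Fold changes are on the log2 scale of RIP over input, with an approximate standard error taken as the size of the log2 fold change divided by the square root of the F statistic. CPM values are TMM-normalized, with mean ± SD over 4 libraries. Gene lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and with an estimated one, and with fry. Of 26 lists, 23 had at least 5 tested members. With the preset correlation camera called 1 list higher and 4 lower, with the estimated correlation 0, and fry called 0 in one direction and 1 for change in either direction. The lowest adjusted p with the estimated correlation was 0.537. Of the 35 splits of the 8 libraries into 4 against 4, the real one included, 25 called at least 5 lists with the preset correlation. The other splits called a median of 7 lists and at most 10, so the number of lists called does not set the real grouping apart. Shares of counts were compared with exact two-sided permutation tests, whose smallest p is 0.0286. A gene with 0 counts in a group has a bound computed against 3 counts per library.

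The gene lists, the design, the naming rule and most alternatives were fixed before the data were examined. The share classes of Tmem38b, Rn45s and the structured small RNA list were added to the planned ones. The rule named the genes past the threshold with expression at or above the median, all RIP libraries on one side of all input libraries and a symbol that is not a predicted model, or the 8 with the lowest p on a side where none passed. It also named Dcp1a, Dcp2, Ddx6, Lsm14b, Edc3, Edc4, Ybx2, Zp3, Gdf9, Figla, Ddx4, Foxl2, Amh and Malat1, and up to 4 members with the lowest p of each list. Of each list without a call only 2 are given here.

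The alternatives tried were other scalings (RLE, upper quartile, library size only, and library sizes without the 10 largest genes), DESeq2 1.42.0, limma voom with sample weights, no filter and a stricter filter on low counts, the replicate number as a block, a fold threshold, an adjusted p threshold of 0.01, and leaving out each library or number. Comparisons within libraries 1 and 2, within libraries 3 and 4, with that grouping as a block, and of RIP 2 to 4 against input 3 and 4 were added after seeing the data. The test was tested on simulated data for RIP against input over 14314 genes with fixed seeds. It recovered 7 of 50 genes changed 2-fold, 44 of 50 changed 4-fold and 50 of 50 changed 8-fold or 16-fold, all of above-median expression, with 8 false calls, and it made 1 call when nothing was changed. Camera called a simulated list of 40 genes changed 2-fold and 0 of 23 unchanged lists. Genes were simulated independently of each other, so this does not show how camera behaves on lists whose members vary together. No grouping of libraries was simulated, so recovery of genes that vary with such a grouping was not tested. In the real data the estimated correlation was 0.752 for the structured small RNAs and 0.551 for histone genes.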

Results

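RNA bound to the decapping co-activator DCP1A was compared with input RNA in the mouse ovary. DCP1A is a component of cytoplasmic processing bodies (P-bodies), where mRNA is stored, deadenylated and decapped. The tissue was ovarian cortex at postnatal day 8, which is rich in primordial and primary follicles. Antibody against DCP1A was used to recover RNA by RNA immunoprecipitation (RIP), and the stated question was which RNAs interact with DCP1A in primary oocytes. The data comprised 4 input and 4 RIP libraries with estimated counts for 23107 genes. Input libraries 1 to 4 held 13098153, 13142790, 25757618 and 25030606 counts, and RIP libraries 1 to 4 held 16325387, 21269891, 20199164 and 18658435 counts. Whether the replicates came from separate animals or pools is not given, so p-values measure only the spread between these samples, which may be technical. No library made with a control antibody was analysed here, so background binding was not measured.

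The 6 genes that fell in the DCP1A RIP were a pair of small nuclear RNA genes, a pair of lncRNA genes and a pair of annotated protein-coding genes. The U11 small nuclear RNA Rnu11, part of the minor spliceosome (mm10 chromosome 4, 132270079 to 132270186), fell from 933 ± 689 CPM in input to 50.7 ± 23.9 CPM in RIP (SD, n = 4 each). The U12 small nuclear RNA Rnu12 of the same machinery (chromosome 15, 83149645 to 83149794) fell from 601 ± 472 to 36.2 ± 12.5 CPM. Gm20594, an annotated gene spanning 334 bp (chromosome 6, 79818031 to 79818364), fell from 3831 ± 1459 to 272 ± 59 CPM. Its annotated synonym, Mtrnr2l, marks it as a nuclear relative of the mitochondrial large ribosomal RNA, so reads of that RNA may be counted in it and its level is uncertain. The lncRNA gene B230208H11Rik (chromosome 10, 12916646 to 12923127) fell from 79.4 ± 61.0 to 2.55 ± 0.45 CPM, and a tRNA gene lies within it at 12922571 to 12922653. Tmem38b, which encodes an intracellular cation channel (chromosome 4, 53825988 to 53862019), fell from 41156 ± 30717 to 961 ± 898 CPM. A ribosomal RNA gene of 119 bp lies within Tmem38b at 53860652 to 53860770, and the counts cannot separate the host from the RNA inside it. BC090627 (chromosome 15, 89416405 to 89429927), which overlaps Cpt1b and Chkb, had 6.66 ± 3.64 CPM in input and 0 counts in RIP, at least 41.2-fold lower against a floor of 3 counts per library. That bound covers counting error only. How reads were divided between BC090627 and the genes it overlaps is not known, so its level is uncertain.

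**Figure D1:**
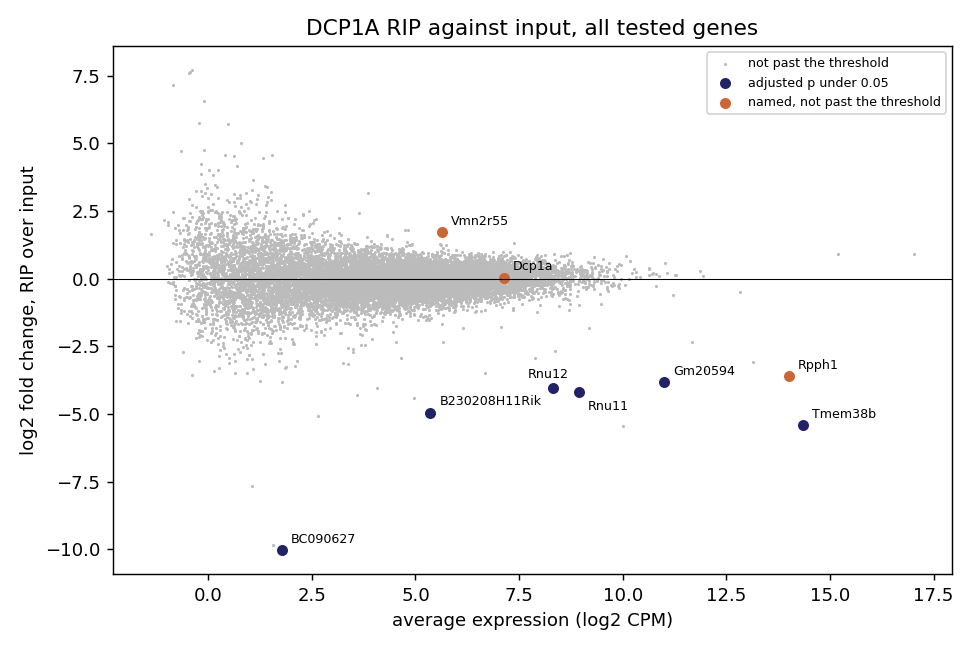
Log2 fold change of RIP over input against average expression (log2 CPM) for each of the 14667 tested genes. The 6 genes past the threshold all lie below 0, while Dcp1a lies at 0.04 and Vmn2r55 at 1.71. The value of BC090627 is a fitted one that depends on the prior count, since its RIP libraries held 0 counts.

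By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes were -3.82 ± 0.33 for Gm20594 (SE, adjusted p = 8.75e-05), -4.20 ± 0.54 for Rnu11 (0.00499) and -4.05 ± 0.53 for Rnu12 (0.00499). They were -4.95 ± 0.65 for B230208H11Rik (0.00499) and -5.42 ± 0.80 for Tmem38b (0.0157), and the adjusted p was 0.0382 for BC090627. Gm20594, B230208H11Rik and BC090627 lay outside the naming rule and were chosen after their values were seen. Of 14667 genes tested, edgeR called 0 higher and 6 lower, with 462 higher and 628 lower at an unadjusted p under 0.05 where 733 were expected by chance in all. DESeq2 called 13 higher and 43 lower, and limma voom with sample weights called 0 higher and 7 lower. The groups did not overlap for 776 genes (5.29%, where chance gives 2.86%), 406 of them higher and 370 lower in RIP. Within libraries numbered 1 and 2, 3 genes passed as higher and 24 as lower. Within libraries numbered 3 and 4 the counts were 0 and 6, and with this grouping as a block over all 8 libraries they were 12 and 43. This grouping was chosen after the data were seen, because setting libraries 1 and 2 against 3 and 4 gave 86 genes. Without input 3 the number of lower genes was 15, and without RIP 1 it was 16. Gm20594, Rnu11, Rnu12 and B230208H11Rik passed in each of the 8 fits without 1 library. Of these, only Gm20594 passed in each of the 4 fits without both libraries of a number. The edgeR adjusted p of Rnu11, Rnu12 and B230208H11Rik was 0.0857, 0.0857 and 0.115 without number 1, 0.0659, 0.0893 and 0.107 without number 2, and 0.0716 each without number 4, while all of them passed without number 3. Within libraries 3 and 4, Rnu12 (edgeR adjusted p = 0.0683), B230208H11Rik (0.5) and BC090627 (0.223) did not pass, and within libraries 1 and 2 BC090627 did not (0.323). Tmem38b did not pass without input 1 (edgeR adjusted p = 0.0736), input 2 (0.0523), RIP 2 (0.101) or RIP 3 (0.0669), nor without number 1 (0.0857), 2 (0.296) or 4 (0.0716). BC090627 did not pass without input 1 (edgeR adjusted p = 0.0736), input 2 (0.0907), input 4 (0.206), RIP 2 (0.128), RIP 3 (0.129) or RIP 4 (0.107), nor without number 1 (0.0857), 2 (0.296), 3 (0.0684) or 4 (0.458). Rnu11, Rnu12 and Tmem38b passed neither limma voom with sample weights (adjusted p = 0.163, 0.0936 and 0.292) nor edgeR without the low-count filter (0.0994, 0.0994 and 0.485). B230208H11Rik did not pass limma voom (0.307), and BC090627 did not pass edgeR with library size alone as the scaling (0.0709).

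Among genes with higher levels in RIP none passed edgeR's main test, and some passed other fits. Vmn2r55, annotated as a vomeronasal receptor, had 23.4 ± 8.9 CPM in input and 76.6 ± 31.2 in RIP (log2 1.71 ± 0.36, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.214). Fam83g was at 31.7 ± 9.0 and 75.5 ± 17.8 CPM, and Smarcd3, a subunit of the BAF chromatin remodelling complex, at 17.6 ± 2.5 and 42.7 ± 13.4 CPM. The receptor kinase gene Grk4 was at 103 ± 19 and 189 ± 10 CPM, the replication-repair factor Tonsl at 41.1 ± 10.1 and 85.3 ± 17.7, and Ranbp3 at 57.3 ± 2.2 and 104 ± 14 CPM. Synj2bp, whose product lies in the mitochondrial outer membrane, was at 125 ± 26 and 230 ± 34 CPM, and Rptor, the scaffold of mTORC1, at 78.9 ± 24.9 and 156 ± 32 CPM. The highest adjusted p among these 8 genes was 0.490, and the rule that named them required all RIP libraries to lie above all input libraries. By DESeq2 the adjusted p was 0.00436 for Vmn2r55, 0.0182 for Fam83g, 0.0365 for Smarcd3 and 0.0461 for Grk4. With the replicate number as a block in edgeR, Vmn2r55 (adjusted p = 0.00844), Fam83g (0.0191) and Rptor (0.0409) passed, and with the number groups as a block Vmn2r55 (0.0119), Fam83g (0.0183) and Grk4 (0.0482) did. Within libraries 1 and 2 or within libraries 3 and 4 none of these 8 genes passed. On simulated data with the spread of these libraries, 7 of 50 genes of above-median expression changed 2-fold were recovered, and 44 of 50 changed 4-fold.

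The structured small noncoding RNAs, a list fixed before the data were examined, were lower in RIP as a group. The RNA subunit of RNase P, Rpph1, was at 30480 ± 17324 CPM in input and 2503 ± 2824 in RIP (log2 -3.61 ± 0.71, n = 4 each). Rmrp, the RNA of RNase MRP, was at 16160 ± 9182 and 1919 ± 2408 CPM. The vault RNA Vaultrc5 was at 1999 ± 1423 and 46.3 ± 60.7 CPM, and the small nucleolar RNA Snord17 at 420 ± 216 and 55.0 ± 43.1 CPM. Scarna2 (log2 0.21 ± 0.39) and the telomerase RNA Terc (0.19 ± 0.78) did not share this direction. Only 9 of the names on this list were analysed, and Rn7sk, Rn7sl1, Rny1, Rny3 and Rnu1a1 were among those that were not. Of 9 members tested, 2 fell over all genes tested by edgeR's main test (Rnu11 and Rnu12) and 7 fell when adjusted over the list alone, the others being Rpph1, Rmrp, Vaultrc5, Snord17 and Rnu73b. Over all genes tested, Snord17, Rpph1 and Vaultrc5 also passed by DESeq2 (adjusted p = 0.00893, 0.0292 and 0.000707), with the number groups as a block in edgeR (1.86e-08, 0.0165 and 0.0064) and with the replicate number as a block (3.67e-09, 3.62e-07 and 0.00128), where Rmrp passed too (0.00025). By limma voom with sample weights Vaultrc5 passed (adjusted p = 0.0216) and Snord17 and Rpph1 did not (0.307 each). In edgeR without a block, Rpph1 passed without input 3 (adjusted p = 0.0244) or RIP 1 (0.00697), and Snord17 without RIP 1 (0.0236). Snord17 passed within libraries 1 and 2 (edgeR adjusted p = 6.69e-06) and within libraries 3 and 4 (0.00266). Rpph1 passed within libraries 1 and 2 (edgeR adjusted p = 0.0066), without number 3 (0.0364) and for RIP 2 to 4 against input 3 and 4 (0.0223), but not within libraries 3 and 4 (0.12). The median log2 fold change was -3.07, and limma's camera test gave an adjusted p of 1.68e-13 with its preset correlation. This call was lost at adjusted p = 0.537 with an estimated correlation, while fry's test for change in either direction gave an adjusted p of 0.0278. The median of the list was -3.18 within libraries 1 and 2 and -3.55 within libraries 3 and 4. Small RNAs with near-identical genomic copies have uncertain counts.

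**Figure D2:**
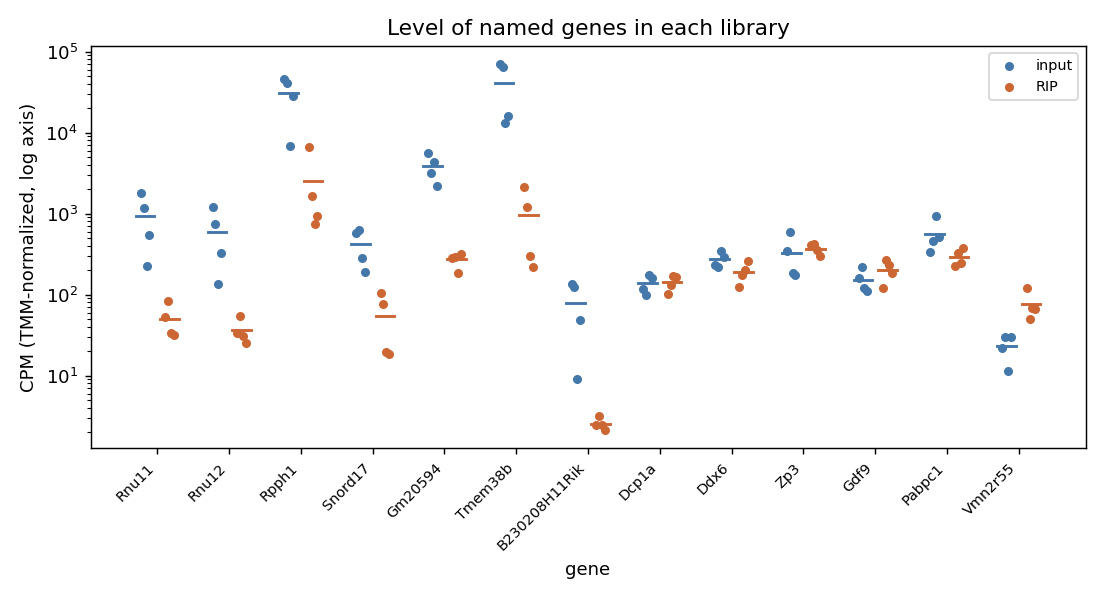
TMM-normalized CPM of 13 named genes on a log axis, with 1 point per library and a bar at the mean of 4 input (blue) or 4 RIP (orange) libraries. For Rnu11 the input libraries span 228 to 1781 CPM and the RIP libraries 32.2 to 83.5 CPM, while for Dcp1a the groups overlap.

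The Dcp1a transcript itself was at 138 ± 35 CPM in input and 142 ± 31 CPM in RIP (log2 0.04 ± 0.26, n = 4 each, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.980). The antibody binds the protein, so this level is no check of the immunoprecipitation. Dcp2, the decapping enzyme, had a log2 fold change of -0.54 ± 0.28, and the P-body helicase Ddx6 one of -0.52 ± 0.26. The decapping scaffolds Edc3 and Edc4 were at 0.07 ± 0.37 and 0.44 ± 0.27, the translational repressor Lsm14b at 0.10 ± 0.26, and the germ cell RNA-binding protein gene Ybx2 at 0.34 ± 0.26. In the list of P-body and decapping genes, Lsm5 had the lowest value of the named members (-1.31 ± 0.45) and the nonsense-mediated decay helicase Upf1 was at 0.65 ± 0.23. Of the 35 members tested, 0 passed edgeR's test over all genes or adjusted over the list alone, with 1 higher and 3 lower at an unadjusted p under 0.05. The list's median was -0.23 and camera's adjusted p was 0.0958. The CCR4-NOT and PAN deadenylase genes, among them Cnot4 (-0.78 ± 0.33) and Btg2 (-0.67 ± 0.30), had a median of -0.15 over 19 members with 0 passing, 2 lower at an unadjusted p under 0.05, and a camera adjusted p of 0.086, which was 0.0315 without RIP 3 (median -0.17) and 0.0413 without RIP 4 (-0.27).

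None of the oocyte transcripts tested passed between input and RIP. The zona pellucida gene Zp3 was at 327 ± 199 CPM in input and 371 ± 54 in RIP (log2 0.18 ± 0.34, n = 4 each). The oocyte growth factor gene Gdf9 was at 154 ± 50 and 201 ± 63 CPM (0.39 ± 0.29), and the transcription factor gene Figla at 48.4 ± 12.3 and 44.8 ± 4.9 CPM (-0.11 ± 0.27). The germ cell helicase gene Ddx4 was at 46.6 ± 25.1 and 29.5 ± 13.2 CPM (-0.66 ± 0.45). Nlrp14 (-0.77 ± 0.27) and the piRNA pathway gene Mael (-0.68 ± 0.26) had the lowest p of the list. Of 52 oocyte genes tested, 0 passed edgeR's test over all genes or adjusted over the list alone, with 1 higher and 4 lower at an unadjusted p under 0.05. The median was -0.08 and camera's adjusted p 0.357. Oocyte genes made up 0.725 ± 0.107% of counts in input and 0.712 ± 0.147% in RIP (exact two-sided permutation test, p = 0.829, n = 4 each).

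Meiosis genes were called lower in RIP as a list by camera with its preset correlation, with no single member passing. The difference in mean log2 CPM was -0.28 ± 0.51 (SE), the groups overlapped, and 11 of 35 splits of the libraries gave a camera p as small. The axial element gene Sycp3 was at 57.7 ± 48.1 CPM in input and 20.8 ± 10.2 in RIP (log2 -1.48 ± 0.48, n = 4 each), and input 3 alone held 129 CPM. Tex15 (-1.23 ± 0.39), the meiotic cohesin gene Smc1b (-0.98 ± 0.45) and the mismatch repair gene Mlh3 (-0.98 ± 0.48) followed. Of 21 members, 15 had a negative fold change, 0 passed edgeR's test over all genes or adjusted over the list alone, and 3 were lower at an unadjusted p under 0.05. The median was -0.54 and camera's adjusted p was 0.0221, lost at adjusted p = 0.84 with an estimated correlation. Without input 3 the median was -0.07 (adjusted p = 0.279), and the call also ended without input 4 (-0.53), RIP 1 (-0.397) or RIP 2 (-0.55), without number 1 (-0.075, adjusted p = 0.104) or number 3 (-0.18, 0.105), by DESeq2 (0.0699), with limma voom (0.0624) and without a low-count filter (0.053), while the median was -0.35 without input 1 and -0.93 without RIP 4. Within libraries 1 and 2 the median was -0.13 (adjusted p = 0.436), within libraries 3 and 4 it was -0.48 (0.0447), and with this grouping as a block it was -0.28.

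Translation factor mRNAs were lower in RIP as a list. The initiation factor gene Eif3e was at 92.3 ± 35.8 CPM in input and 45.4 ± 9.9 in RIP (log2 -1.02 ± 0.30, n = 4 each). The poly(A)-binding protein gene Pabpc1 was at 561 ± 256 and 293 ± 69 CPM (-0.94 ± 0.30), Tpt1 at 934 ± 422 and 492 ± 90 CPM (-0.92 ± 0.29), and the initiation factor gene Eif2s3x at 186 ± 31 and 111 ± 21 CPM (-0.75 ± 0.24). Of 34 members, 26 had a negative fold change, 11 were lower at an unadjusted p under 0.05, and 0 passed edgeR's test over all genes or adjusted over the list alone. The median was -0.30 and camera's adjusted p was 0.000143, lost at adjusted p = 0.642 with an estimated correlation. The median was -0.15 within libraries 1 and 2 and -0.45 within libraries 3 and 4, with camera's adjusted p at 0.0452 and 1e-04. Without input 3, which had the highest mean level of this list, the median was -0.14.

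Nuclear-encoded respiratory chain genes were also called lower as a list by camera with its preset correlation, but the groups overlapped. The difference in mean log2 CPM was -0.25 ± 0.20 (SE). Input 4 had a mean of 5.56, below all RIP libraries (5.62 to 5.91), and 15 of 35 splits of the libraries gave a camera p as small. The ATP synthase subunit genes Atp5e and Atp5j had log2 fold changes of -1.12 ± 0.37 and -0.69 ± 0.25, the cytochrome c oxidase gene Cox7b one of -1.03 ± 0.37 and the complex III gene Uqcrb one of -1.27 ± 0.46 (SE, n = 4 each). Of 52 members, 42 had a negative fold change, 8 were lower at an unadjusted p under 0.05, and 0 passed edgeR's test over all genes or adjusted over the list alone. The median was -0.29 and camera's adjusted p 0.00291, lost at adjusted p = 0.84 with an estimated correlation. The call ended without input 1 (-0.26), input 2 (-0.16), RIP 4 (-0.22) or number 2 (-0.15). Within libraries 1 and 2 the median was -0.35, and within libraries 3 and 4 it was -0.13 (adjusted p = 0.351). Ribosomal protein genes and mitochondrially encoded mRNAs were not analysed here.

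Replication-dependent histone genes, a list set by symbol pattern, were higher in RIP as a list. The mRNAs of such genes end in a stem-loop without a poly(A) tail, but whether each matched gene is of this kind was not checked. Hist1h4d was at 92.2 ± 44.3 CPM in input and 185 ± 73 in RIP (log2 1.00 ± 0.36, n = 4 each), and Hist1h2ac at 32.3 ± 18.3 and 65.3 ± 19.1 CPM (1.02 ± 0.39). Hist1h3c (1.12 ± 0.46) and Hist1h2ag (1.19 ± 0.49) lay in the same direction. Of 59 members, 54 had a positive fold change, 12 were higher at an unadjusted p under 0.05, and 0 passed edgeR's test over all genes or adjusted over the list alone. The median was 0.57 and camera's adjusted p 2.69e-16, lost at adjusted p = 0.642 with an estimated correlation. The median was 0.47 within libraries 1 and 2 and 0.99 within libraries 3 and 4, was 0.34 without RIP 1, and was 0.93 without input 2. Hist1h4d passed over all genes in edgeR with the replicate number (adjusted p = 0.027) or the number groups (0.0248) as a block, and Hist1h2ac for RIP 2 to 4 against input 3 and 4 (0.0474). Histone genes are near-identical in sequence, so the counts of single members are uncertain.

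**Figure D3:**
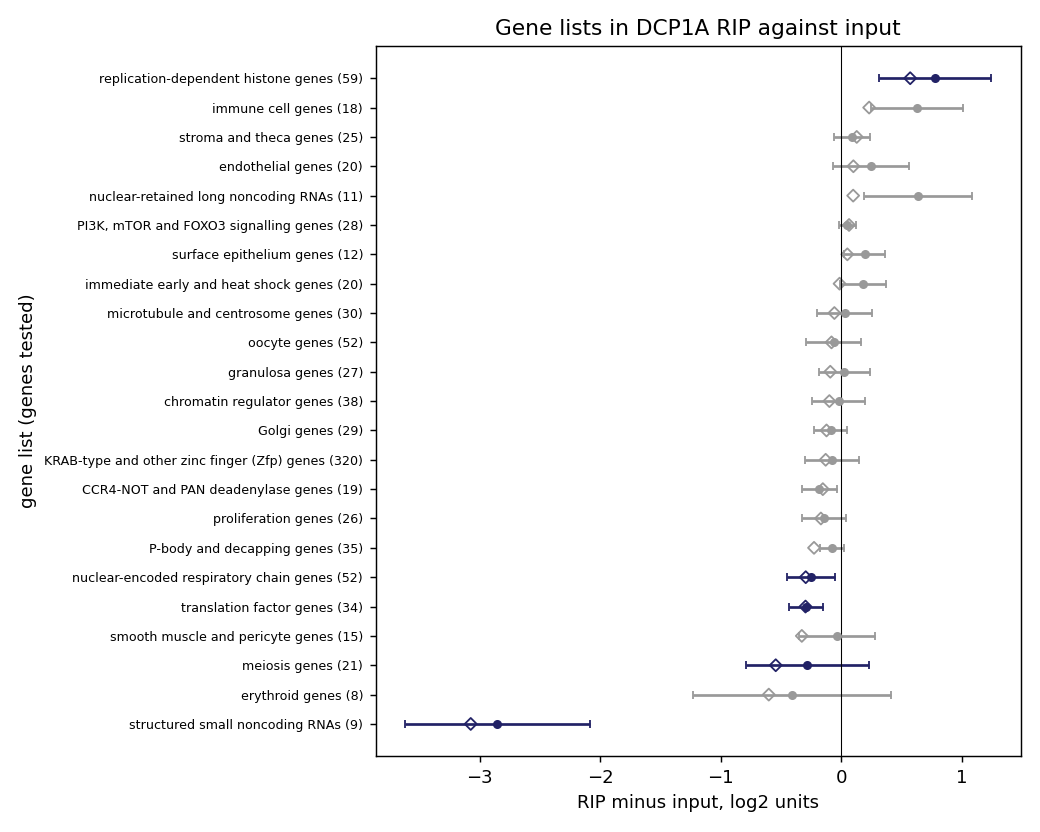
RIP minus input in log2 units for the 23 tested gene lists. Filled points are the difference of the mean log2 CPM over members with its SE over 4 against 4 libraries, open diamonds the median log2 fold change, and dark colour a camera adjusted p under 0.05 with the preset correlation. The structured small noncoding RNAs lie at -2.85 and -3.07, and the next lowest median is -0.60.

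Genes of the somatic cells of the ovary gave no list call over all 8 libraries by the main test. The granulosa genes Foxl2 and Amh had log2 fold changes of -0.01 ± 0.27, which became 0.02 under upper-quartile scaling, and 0.03 ± 0.36, and Kitl and the aromatase gene Cyp19a1 had -0.63 ± 0.27 and 2.76 ± 1.5 (SE, n = 4 each). The stroma genes Dcn and Nr2f2 were at -0.81 ± 0.29 and -0.69 ± 0.27, and the endothelial genes Erg and Flt4 at -1.21 ± 0.86 and 0.75 ± 0.55. The macrophage genes Csf1r and Lyz2 were at 0.84 ± 0.38 and -1.47 ± 0.77, and the surface epithelium genes Krt8 and Igfbp5 at 0.67 ± 0.27 and -0.34 ± 0.27. Notch3 and Myl9 of smooth muscle and pericytes were at 0.74 ± 0.38 and 0.64 ± 0.34, and the erythroid genes Hbb-bs and Slc4a1 at -0.98 ± 0.47 and -1.43 ± 0.85. List medians were -0.09 for granulosa, 0.13 for stroma and theca, 0.10 for endothelial, 0.23 for immune, 0.05 for surface epithelium (-0.03 with library size alone as the scaling), -0.33 for smooth muscle and -0.60 for erythroid genes. Camera's adjusted p for these lists lay between 0.0958 for immune cell genes and 0.935 for smooth muscle genes, and 0 of their members passed edgeR's test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 granulosa genes had 1 lower, stroma genes 3 lower, and immune and surface epithelium genes 1 higher each. For granulosa and smooth muscle genes fry's direction was up while the median was negative, and for endothelial genes the mean log2 fold change was -0.0055 while the median was positive. Granulosa genes were called lower within libraries 1 and 2 (median -0.29, camera adjusted p = 0.038) but not within libraries 3 and 4 (0.14, 0.153), and higher for RIP 2 to 4 against input 3 and 4 (0.22, 0.0179). Immune cell genes were called higher without input 3 (0.25, camera adjusted p = 0.0132), without number 3 (0.40, 0.026) and with limma voom and sample weights (1.42, 0.0407). Their median was -0.10 without RIP 2 (camera adjusted p = 0.149), 0.70 without input 2 (0.179) and -0.056 without a low-count filter (0.163), and none of these was a call. Erythroid genes were called lower with the replicate number as a block (-0.053, camera adjusted p = 0.0338), and their median was 0.11 with limma voom. Only 3 of 12 adipocyte genes were tested, fewer than the minimum of 5.

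Signalling, chromatin and stress genes gave no list call over all 8 libraries by the main test. In the list of PI3K, mTOR and FOXO3 signalling genes, which control primordial follicle activation, Rptor (log2 0.99 ± 0.27) and Tsc2 (0.72 ± 0.26) were the members with the lowest p, and the median over 28 members was 0.07 (camera adjusted p = 0.824). The chromatin regulators Trrap (0.51 ± 0.24) and Suz12 (-0.88 ± 0.42) belonged to a list with a median of -0.10 (0.809). The centrosome gene Pcm1 (-0.87 ± 0.42) and Mtcl1 (0.42 ± 0.24) were in a list with a median of -0.06 (0.809), and Copb1 (-0.72 ± 0.31) and Golga5 (-0.74 ± 0.36) of the Golgi in one with a median of -0.12 (0.246). Zfp68 (-0.97 ± 0.31) and Zfp563 (-1.63 ± 0.59) had the lowest p of 320 zinc finger genes, whose median was -0.13 (0.126). Birc5 (-0.64 ± 0.26) and Mcm3 (0.67 ± 0.29) stood for 26 proliferation genes with a median of -0.17 (0.246). Malat1, a nuclear lncRNA, was at -0.48 ± 0.47 and Kcnq1ot1 at 0.88 ± 0.29 (edgeR adjusted p = 0.0453 with the replicate number as a block), and the nuclear-retained lncRNAs had a median of 0.10 (0.162), with Mirg at 2.63 ± 1.54. The heat shock gene Hspa1a had 0 counts in all 4 input libraries and 14 to 36 in the RIP libraries, at least 7.1-fold higher against a floor of 3 counts per library, and did not pass (adjusted p = 0.532, edgeR). Its near-identical neighbour Hspa1b was at 0.69 ± 1.57, so the division of reads between the pair is uncertain, and Egr2 was at -0.98 ± 0.39. The immediate early and heat shock list had a median of -0.01, which became 0.02 under upper-quartile scaling, and a mean of 0.33, with camera's direction down (0.646). Within libraries 3 and 4 this list was called lower (median -0.41, camera adjusted p = 0.00218), while within libraries 1 and 2 its median was 0.33 (0.0751). Chromatin regulator genes were called lower within libraries 3 and 4 (-0.18, camera adjusted p = 0.0447) and higher within libraries 1 and 2 (0.17, 0.0452). For RIP 2 to 4 against input 3 and 4, chromatin (-0.30, camera adjusted p = 0.00946), immediate early and heat shock (-0.31, 0.00536) and zinc finger genes (-0.28, 0.0279) were called lower. Zinc finger genes were also called lower without input 2 (-0.26, camera adjusted p = 0.046) and without a low-count filter (-0.15, 0.049), and nuclear-retained lncRNAs higher without input 4 (0.39, 0.0143).

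The shares of counts held by RNase P and RNase MRP RNAs, small nuclear RNAs and Tmem38b were lower in all 4 RIP libraries than in all 4 input libraries. The RNAs of RNase P and RNase MRP made up 5.20 ± 2.56% of counts in input and 0.462 ± 0.466% in RIP (SD, n = 4 each), and small nuclear RNAs 0.145 ± 0.099% and 0.00855 ± 0.00338%. Tmem38b made up 3.87 ± 2.60% and 0.0878 ± 0.0730%. Each of these differences reached p = 0.0286, the smallest that the exact two-sided permutation test of 4 against 4 allows, and 0.0714 after Benjamini-Hochberg adjustment over 10 classes. Tmem38b, Rn45s and the structured small RNA list were not among the classes planned beforehand. Tmem38b had already been named as a gene whose groups did not overlap, so its p adds no separate evidence. The gene Rn45s, annotated as 45S pre-ribosomal RNA, made up 8.85 ± 3.91% of input and 17.0 ± 3.7% of RIP counts (exact permutation p = 0.0857, adjusted 0.143). Whether these reads came from the precursor or from mature ribosomal RNA was not determined. Small nucleolar RNAs made up 0.458 ± 0.229% and 0.253 ± 0.112% (exact permutation p = 0.229), lncRNAs 2.28 ± 0.49% and 1.5 ± 0.40% (0.0571), and protein-coding genes 81.8 ± 6.1% and 79.6 ± 3.7% (0.714). The protein-coding class includes Tmem38b, and also Lars2, which held 1.28 to 3.85% of counts in input and 1.58 to 9.62% in RIP libraries. The structured small RNA list made up 4.87 ± 2.48% and 0.419 ± 0.424% (exact permutation p = 0.0286), and the 10 genes with most counts 22.8 ± 9.4% and 24.3 ± 6.6% (0.8).

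**Figure D4:**
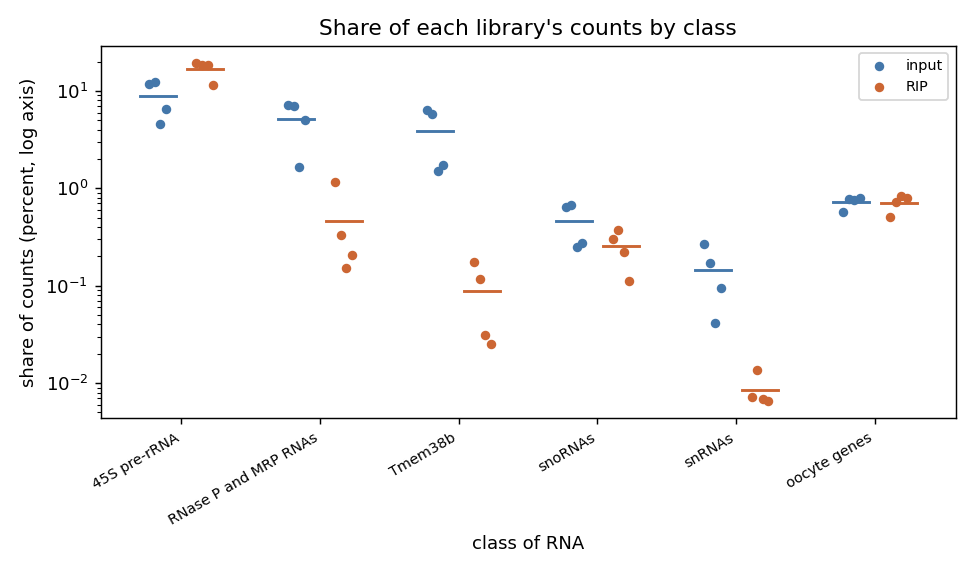
Share of each library's counts (percent, log axis) for 6 classes of RNA, with 1 point per library and a bar at the mean of 4 input (blue) or 4 RIP (orange) libraries. The groups do not overlap for the RNase P and MRP RNAs, Tmem38b and the small nuclear RNAs, and they overlap for oocyte genes.

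Across 13664 protein-coding genes the log2 fold change had a Spearman correlation of -0.0897 with the annotated gene span, a relation across genes, which are not independent replicates. Pairing input and RIP libraries by number gave -0.0813, 0.0785, -0.16 and -0.0643 for numbers 1 to 4, so the sign was not shared. Protein-coding genes spanning 350 to 1000 bp, of which most were histone genes, had a median log2 fold change of 0.48 over 90 genes, and noncoding RNAs of up to 350 bp one of -1.16 over 119 genes.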

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

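The tests of short RNAs, nuclear RNA, dividing cells the grouping of libraries 1 and 2 against 3 and 4, and splits within that grouping were chosen only after the results were seen, as was leaving out single receptor genes. In each group of 4 libraries a highest or lowest value was marked when its gap to the nearest other exceeded Dixon's critical value. Of 228 groups tested 16 were marked, where chance alone marks about 1 in 20 (11.4 here), and 5 of the 16 lay in input 3 and 4 in RIP 1.

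In input 3, Sycp3 was at 129 CPM, Suz12 at 102, Golga5 at 70.9 and Tpt1 at 1558, each above the other input libraries, and the mean log2 CPM of the translation factor genes was 8.04. In input 4, Dcp2 was at 125.5 CPM, the highest, and oocyte genes made up 0.566% of input 1, the lowest share. In RIP 1, Nlrp14 was at 94.8 CPM and Copb1 at 24.7, below the other RIP libraries, while Rpph1 was at 6701 CPM and Hist1h3c at 45.8, above them. In RIP 2, Hbb-bs was at 127 CPM, Slc4a1 at 18.9 and the share of small nuclear RNAs at 0.0136%, each the highest of the RIP libraries. In RIP 4, Rn45s made up 11.5% of counts, the lowest share, and the PI3K, mTOR and FOXO3 list had the highest mean log2 CPM, 6.66.

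Small structured RNAs were lower in RIP as a list. Scaling to library size alone left the list's median at -3.19, and it moved the median of all tested genes only from -0.0211 to -0.0351. The highest median of the list without any 1 library was -2.75. The nuclear-retained lncRNAs had a difference in mean log2 CPM of 0.63 ± 0.45 (SE; median log2 fold change 0.10). Of these 11 lncRNAs 6 had a positive fold change, and Malat1 was at -0.48 ± 0.47. These values argue against the TMM factors, a single library or a loss of nuclear RNA as the whole cause. A loss of all RNAs under about 1 kb is argued against by short protein-coding genes, at 0.505 ± 0.32 for 91 genes and 0.0669 ± 0.135 for the 37 that are not histone genes, though the bound of -1 for these 37 was set after their value was seen and a first bound of 0 had left the question undecided. A loss of RNAs under about 350 nt cannot be told apart from a difference in binding, since noncoding RNAs of that span had a median of -1.16 and only 1 protein-coding gene of that span, Gm20594, was tested, itself lower. Of the 35 splits of the 8 libraries 3 gave a camera p as small for this list (real 1.46e-14, smallest of the others 4.13e-17), so chance could not be excluded by splits that exchange libraries across number groups, while within number groups, with these as a block, the real split gave 1.86e-27 and the smallest of the others was 5.07e-12, with too few splits (18) for a share under 0.05. Lower binding to DCP1A than to other RNA stays an open hypothesis, as does uneven recovery of short RNA between input and RIP preparations.

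Histone genes were higher in RIP as a list, with 0 of 59 members passing edgeR's main test. Camera's call for the list was lost with an estimated correlation (adjusted p = 0.642). The score difference was positive within libraries 1 and 2 (0.476) and within libraries 3 and 4 (1.08). Each of these groups holds as many input as RIP libraries, so an even shift between the groups cancels by design whatever these values are. The proliferation genes, with a difference in mean log2 CPM of -0.14 ± 0.18 (SE; median log2 fold change -0.17), left a larger share of dividing cells undecided. For genomic DNA or unspliced RNA in the RIP libraries, olfactory and vomeronasal receptor genes, expressed mainly in sensory tissue, were examined. Their log2 ratio was 0.407 ± 0.216 against 0.582 ± 0.366 for histone genes, which met the bound set beforehand. Meeting it rests on Vmn2r55, without which the ratio was 0.167 ± 0.25 and below the bound. Without Olfr613, the receptor gene with most counts, the ratio was 0.415 ± 0.188. The ratio takes no account of level. All 1429 receptor genes together held 2111 to 8935 counts per library, and the 68 histone genes 44312 to 111284. Genomic DNA spread evenly over genes would add few counts to histone genes, which argues against it as the cause. Unspliced RNA was not tested separately. Of 35 splits 9 gave a camera p as small (real 1.17e-17, smallest of the others 8.84e-29), so chance could not be excluded, the 18 splits within number groups gave 6.45e-17 against 2.11e-17, and binding of histone mRNA by DCP1A was not tested separately.

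The count of 6 genes was reached by 2 of 35 splits, so chance could not be excluded by this measure, which exchanges libraries across number groups. The other was libraries 1 and 2 against 3 and 4, which gave 86 genes, several times the real count, and points to a structure of the samples. With that grouping as a block 12 genes were higher and 43 lower, and these 43 included all 6, and among the 18 splits that keep 2 libraries of each number group on each side, with the same block, the real one gave 55 genes (1 of 18 as many) and the highest other 1, but 18 splits are too few for a share under 0.05. Of the other called lists, a camera p as small was given by 11 of 35 splits for meiosis genes (real 0.00481, smallest of the others 0.000108) and by 15 for respiratory chain genes (real 0.000506, smallest of the others 2.79e-16), so chance could not be excluded, and within number groups these were 0.00849 against 0.00407 and 0.000238 against 1.9e-08. For translation factor genes 1 of 35 splits, the real one, gave one as small (1.86e-05, next 2.37e-05), a share under 0.05 for this list alone but not over the 5 lists examined, and within number groups the real split gave 6.42e-06 against 1.16e-05, so chance was not taken as excluded.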

How the results depend on the processing

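The comparisons within libraries 1 and 2, within libraries 3 and 4, with that grouping as a block, and of RIP 2 to 4 against input 3 and 4 were chosen after seeing the data, and the other alternatives were planned. Planned checks of transcript length, 3' UTR length and GC content were not run. The counts of 0 higher and 6 lower genes were 13 and 43 by DESeq2, 12 and 43 with the number groups as a block, 3 and 24 within libraries 1 and 2, and 3 and 13 for RIP 2 to 4 against input 3 and 4. Leaving out 1 library or number gave 0 to 1 higher and 1 to 16 lower genes. The 6 genes were all among the calls of DESeq2 and of both blocks, and 2 of them were among the 7 of limma voom. RLE, upper-quartile and library-size scaling kept 6, 6 and 5 of them. On data simulated with the depth and spread of these libraries 2-fold changes were mostly missed and 4-fold changes mostly found. Depth was not varied by itself, so its share in this limit was not tested. No grouping of libraries was simulated. In the real data Rpph1 and Vaultrc5, 12.2-fold and 43.3-fold lower, did not pass edgeR's main test (adjusted p = 0.173 and 0.258). Of the values for lists and genes that turned direction, most were not past the threshold, and the cause was not tested.

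With the replicate number as a block, 13 genes were higher and 42 lower. Correlations of same-numbered libraries' deviations were 0.162, 0.0915, 0.178 and 0.118, all positive. Of the inputs only input 1 correlated best with the RIP library of its own number. Inputs 2, 3 and 4 correlated best with RIP 1, 4 and 3, each within the same number group. The numbers were not taken to pair the samples in the main fit, but these values do not exclude pairing. With this block the medians were -0.060 for granulosa, 0.057 for smooth muscle genes and 0.022 for Foxl2.

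A list is counted as turned when its test changed direction. By DESeq2 the medians were -0.55 for meiosis genes, no longer past the threshold, and -0.015 for immediate early genes. With limma voom and sample weights they were 0.089 for oocyte, 0.049 for stroma, -0.086 for smooth muscle, 0.034 for PI3K and -0.34 for meiosis genes, whose call ended. Without a low-count filter meiosis genes were at -0.73 and their call also ended, and with 10 counts in every library of a group smooth muscle genes were at 0.025. Foxl2 was at 0.022 with upper-quartile factors. With an estimated correlation, and by fry, the calls of meiosis (-0.54), respiratory chain (-0.29), translation factor (-0.30), structured small RNA (-3.07) and histone genes (0.57) ended, their medians being unmoved by construction. Fry's direction was opposite to camera's for granulosa (-0.090) and smooth muscle genes (-0.33).

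In 24 further fits of lists the median changed sign while the test did not, none past the threshold. Besides fits without a library or number, these were -0.056 for immune cell genes without a low-count filter, -0.033 for surface epithelium genes with library size only, and 0.022 for immediate early genes with upper-quartile factors. With limma voom they were 0.11 for erythroid, 0.011 for microtubule and 0.031 for proliferation genes, and within libraries 3 and 4 they were 0.056 for smooth muscle and -0.10 for PI3K genes. Microtubule and immediate early genes were at 0.011 and 0.013 with the replicate number as a block and at 0.016 and 0.024 with the number groups as a block.

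Within libraries 1 and 2 the medians were -0.019 for smooth muscle, -0.71 for erythroid, -0.13 for meiosis, 0.17 for chromatin, 0.16 for microtubule, 0.33 for immediate early and 0.034 for zinc finger genes. There Edc3 was at -0.30, Zp3 at -0.20, Figla at 0.095, Amh at -0.35, Malat1 at 0.040 and Igfbp5 at 0.091. Within libraries 3 and 4 the medians were -0.063 for oocyte, 0.14 for granulosa, 0.026 for endothelial, -0.11 for surface epithelium and -0.13 for respiratory chain genes, with Dcp1a at -0.0067, Lsm14b at -0.034 and Foxl2 at 0.19. With the number groups as a block endothelial genes were at 0.18, smooth muscle genes at -0.29 and Foxl2 at 0.026. For RIP 2 to 4 against input 3 and 4 the medians were 0.22 for granulosa, -0.18 for endothelial, 0.040 for surface epithelium, -0.021 for PI3K, -0.055 for respiratory chain genes and -0.0997 for nuclear lncRNAs, with Dcp1a at -0.102, Lsm14b at -0.11 and Foxl2 at 0.31.

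Leaving out 1 library or number, medians ran from -0.26 to 0.11 for granulosa, 0.015 to 0.23 for stroma, -0.055 to 0.19 for endothelial, -0.31 to 0.27 for surface epithelium, -0.50 to 0.20 for smooth muscle and -0.97 to 0.13 for erythroid genes. They ran from -0.062 to 0.17 for PI3K, -0.24 to 0.13 for chromatin, -0.17 to 0.12 for microtubule and -0.23 to 0.13 for immediate early genes. Meiosis genes ran from -0.93 to -0.069 and respiratory chain genes from -0.39 to -0.15. Immune cell genes ran from -0.097 to 0.70, proliferation genes from -0.23 to 0.027 and zinc finger genes from -0.26 to 0.010. Dcp1a ran from -0.086 to 0.18, Lsm14b from -0.078 to 0.27, Edc3 from -0.16 to 0.61, Zp3 from -0.022 to 0.65, Figla from -0.25 to 0.025, Foxl2 from -0.16 to 0.15, Amh from -0.23 to 0.36 and Malat1 from -0.75 to 0.26. Over all alternatives camera's and fry's adjusted p ran from 0.00821 to 0.862 for meiosis, from 1.49e-07 to 0.96 for respiratory chain and from 2.08e-05 to 0.642 for translation factor genes.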

Other observations

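The small nucleolar RNA class and the genes called by other tools were examined only after the main results were seen. Of 90 small nucleolar RNA genes tested, 77 had a negative fold change, 31 were lower and 1 higher at an unadjusted p under 0.05, and the median log2 fold change was -1.06. Camera's adjusted p over 8 biotypes was 1.14e-06, lost at adjusted p = 0.717 with an estimated correlation. These genes lie mostly within introns of host genes, so reads of the host cannot be separated from theirs. Of the 8 guide RNA genes 5 had a negative fold change, with a median of -1.21 and no call (camera adjusted p = 0.135, and 0.717 with an estimated correlation). The 598 lncRNA genes had a median of 0.19 (camera adjusted p = 0.0393, and 0.717 with an estimated correlation).

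Several abundant mRNAs were lower by DESeq2 and with the number groups as a block, but not by edgeR's main test. The actin-binding thymosin gene Tmsb4x was at 110 ± 55 CPM in input and 31.0 ± 10.9 in RIP (n = 4 each), with a DESeq2 adjusted p of 0.000823 and an edgeR adjusted p of 0.18. The selenoprotein gene Sepp1 was at 123 ± 29 and 53.4 ± 11.5 CPM (DESeq2 adjusted p = 0.00504, edgeR 0.215), and B2m at 134 ± 49 and 57.8 ± 10.5 CPM (DESeq2 adjusted p = 0.0391, edgeR 0.376). These genes were chosen after their values were seen.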
